A study of Mus musculus with 18 samples.

How the data were processed

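Lateral cortices of C57BL/6 mouse embryos at embryonic day 14.5 were dissociated after the meninges and the ganglionic eminences had been taken off, and cells were sorted on a red and a green fluorescent reporter, per the labels' protocols. The protocols give a purity sorting mode at a low temperature, pools of more than 3 embryos of different litters per sample, and poly-A RNA of high integrity that was fragmented and made into cDNA with random primers. The series design states biological replicates, so p-values measure the spread between pools of embryos. The labels give 18 samples, which are 9 libraries (3 of proliferating progenitors, PP, 3 of differentiating progenitors, DP, and 3 of neurons, Neuron), each sequenced in a single-read and in a paired-end run.

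Gene counts were made by the authors and deposited as whole numbers per gene for each run, with 37620 Ensembl release 67 genes and 630 unannotated transcripts in the count tables, per the file headers. The submitters' processing notes name bcl2fastq 1.8.2, TopHat2 2.0.10, Bowtie2 2.2.1, Cufflinks 2.1.1, bedtools 2.16.2, BWA 0.5.9-r16, featureCounts 1.4.4, DESeq2 1.4.5 and DESeq, with no role or order, and the genome build mm9. The deposited comparison tables also hold a normalised signal per library. In these tables, 159606 of 159606 values of annotated genes and 3780 of 3780 of unannotated transcripts per comparison equalled the counts of both runs added and divided by 1 size factor per library, within a tolerance of 0.06. The log2 fold changes in the deposited tables are the authors' own, for DP against PP and for Neuron against DP. Their standard error and test statistic stand there as a score per gene, per the file headers. The authors' p-value and adjusted p stand beside them, and an adjusted p they left empty was kept empty here. Whether counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Near-identical genes (Hba-a1 and Hba-a2, Hbb-b1 and Hbb-b2, ribosomal protein genes and Gapdh) are uncertain because counting can split their reads.

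Count columns carry library numbers that no sample label gives, so a column was tied to its group and not to a replicate number. Libraries are named here by group and library number. The counts of the single-read and the paired-end run of a library were added, since they are 1 replicate. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom lay between 8.48 and 31.27 for different libraries. It lay between 25.64 and 37.17 for the 2 runs of 1 library.

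Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, the quasi-likelihood test on all 9 libraries with the group as the only term and Benjamini-Hochberg adjustment at 0.05 over all features tested. The tests ran on 18627 features: 14718 protein-coding genes, 1465 annotated long non-coding RNAs, 1960 other annotated genes and 484 unannotated transcripts. Levels are CPM, a gene's counts scaled to the TMM-scaled total of the library, computed here from the counts the authors deposited, as mean ± SD over the 3 libraries of a group. Folds are fitted values, and a fold lower is the inverse of the fitted fold. A gene counted as higher in DP than in both when it was past the threshold in DP against PP and in Neuron against DP with DP the higher in each, and as lower in DP likewise.

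The design, the test, the other settings to try, 29 gene lists with 716 different genes and the rule for naming genes were fixed before the data were examined. The lists are radial glia, intermediate progenitors, pan-neuronal genes, cortical projection neuron layer identity, Cajal-Retzius and preplate cells, ventral progenitors and GABAergic interneurons, the Notch pathway, S phase, G2 and M phase, axon guidance, synaptic vesicle release, ion channels and glutamate receptors, glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, immediate early and heat shock genes, progenitor and neuronal BAF complex subunits, neuronal splicing and RNA-binding proteins, Wnt signalling, endothelial cells, pericytes, microglia, red blood cells, oligodendrocyte precursors, meningeal fibroblasts, choroid plexus and cortical hem, and known long non-coding RNAs. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over all lists and both steps, and again with an estimated correlation. The count of its members past the threshold over all features stands beside the count adjusted over the list alone. A symbol with several identifiers (Cux2, Fzd10, Gsx2, Six3, Ebf1, Scn8a, Efna5 and Flrt3) was taken as the one with the most reads.

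The rule named the sort genes Btg2 and Tubb3, and the 10 genes with the highest and the 10 with the lowest log2 fold change per step. These had to be past the threshold, have at least 10 CPM in the higher group and no overlap between the libraries of the groups, and not be pseudogenes or known only by a clone or model number. For Neuron against PP it took 5 of each. It also named up to 3 members per list, step and direction by the lowest adjusted p, and markers of other cell types over 50 CPM in any library. Genes higher or lower in DP than in both were ranked by the smaller of their changes, with at least 10 CPM, and the leading 12 and 6 taken. Long non-coding RNAs were the 3 largest changes per step and direction with at least 2 CPM, and known ones past the threshold in both steps. Unannotated transcripts were the 3 largest changes per direction in each of the authors' deposited tables with a mean of at least 50 in their units, and 5 that were higher in DP. Some genes that the rule takes are not reported here.

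The test was tried on counts simulated for all 9 libraries over 18627 features, from each feature's mean over all of them and the library sizes. In each of 5 draws, 200 genes above a low mean level were changed in DP. The test of DP against PP recovered 59.7% of the genes changed by 1.5-fold and 83.3% of those changed by 2-fold. Of those changed by 4-fold it recovered 99.1%, with 61 false calls among 867. Far fewer genes were changed than are called in the data, so these shares are not the power of the real comparisons. Camera called a simulated rise of the Notch list with an adjusted p of 1.18e-62 and none of 52 tests of lists without its genes. Simulated genes were drawn independently of each other, so this does not test the preset correlation. Other splits of the real libraries called up to 16 lists in DP against PP and up to 20 in Neuron against DP. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter, a mean of at least 1 CPM, each run alone, a fit of only the 2 groups compared, an adjusted p of 0.01, a test against a fold of 1.5, each library left out in turn, stricter thresholds on the authors' adjusted p, a block of library-number sets and the loss of libraries L222, L223 and L224 together. Coordinates are those of the deposited tables on mm9. The reference genome at hand is of another build and was not used here. Depth per library was at least 34337209 counts, and the biological coefficient of variation was 11.3%.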

Results

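The data are RNA counts of 3 cell fractions sorted from the lateral cortex of mouse embryos at embryonic day 14.5. This is a stage at which dividing progenitors and newborn neurons lie side by side in the cortical wall. The embryos carried a reporter at Btg2, an antiproliferative gene switched on in progenitors about to form neurons, and a reporter at Tubb3, a tubulin of neurons. Cells without the red signal are labelled proliferating progenitors (PP), red cells differentiating progenitors (DP) and green cells neurons (Neuron). The titles write RFP for the Btg2 fractions while the genotype label writes GFP for both genes, so the colour is taken from the titles. Each fraction had 3 libraries. Counts per library were 34337209, 43145504 and 43520336 in PP, 41197738, 50535080 and 39836073 in DP, and 49304625, 55935128 and 42840710 in Neuron. Mitochondrial genes took 1.14% to 1.42% of a library and the 10 most counted genes 2.09% to 3.5%. Rank correlations across genes were 0.993 to 0.997 within a group and 0.829 to 0.977 between groups. A principal component holding 93.3% of the variance of the 500 most variable genes ordered PP, DP and Neuron.

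Levels are CPM, mean ± SD over the 3 libraries of a group (n = 3), throughout. The sort genes followed the gates. Btg2 (chromosome 1, 135971747 to 135975697, mm9) stood at 445 ± 67.6 in PP, 888 ± 251 in DP and 169 ± 22.2 in Neuron. It was 1.99-fold higher in DP than in PP (log2 1.00, adjusted p = 0.00106) and 5.26-fold lower in Neuron than in DP (log2 -2.39, adjusted p = 3.75e-07) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tubb3 stood at 87.9 ± 29.5 in PP, 581 ± 98.9 in DP and 2384 ± 261 in Neuron, 6.62-fold higher in DP than in PP and 4.1-fold higher in Neuron than in DP (adjusted p = 2.27e-06 and 3.69e-06, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). In the authors' deposited table the log2 fold changes were 0.99 and -2.35 for Btg2 and 2.71 and 2.05 for Tubb3.

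**Figure D1:**
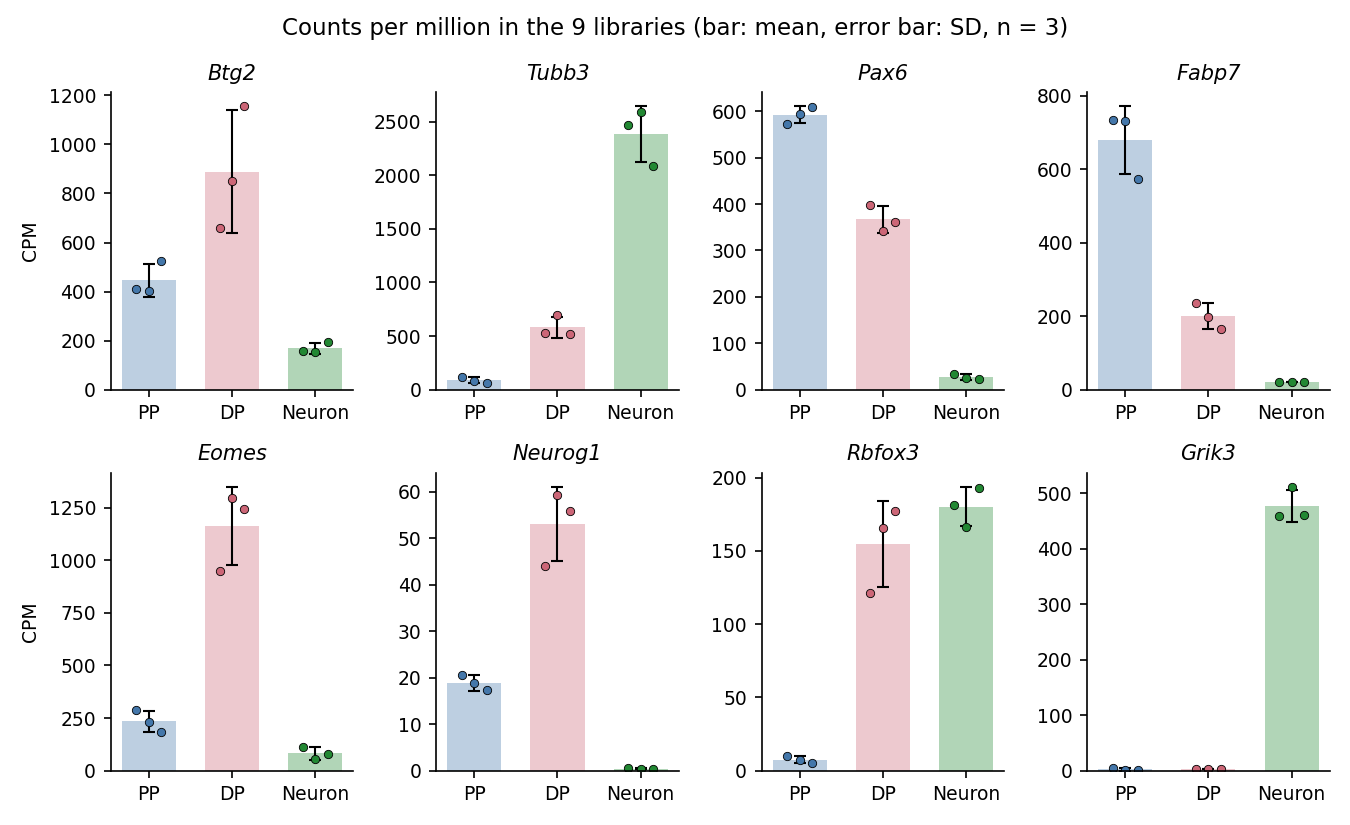
CPM of Btg2, Tubb3, Pax6, Fabp7, Eomes, Neurog1, Rbfox3 and Grik3 (y axis) in PP, DP and Neuron (x axis), with bars for the mean, error bars for the SD and points for the 3 libraries of each group. Eomes and Neurog1 peaked in DP, at 1162 ± 185 and 53.0 ± 7.94, while Grik3 stood at 3.26 ± 0.318 in DP and 477 ± 29.5 in Neuron.

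The comparison of DP with PP asks which transcripts differ between progenitors that divide to make more progenitors and those that turn to making neurons. The 10 genes highest in DP included transcription factors of neuronal differentiation. Nhlh2, a basic helix-loop-helix factor, rose from 0.549 ± 0.153 to 23.9 ± 3.31 (44.3-fold). Neurod1, a factor of the same family, rose from 6.73 ± 3.12 to 152 ± 30 (22.9-fold), and St18, a zinc finger factor, from 1.86 ± 0.0889 to 49.6 ± 5.60 (26.7-fold). Rbfox3, the splicing factor also called NeuN, rose from 7.60 ± 2.33 to 154.7 ± 29.6 (20.5-fold). Slc17a6, a vesicular glutamate transporter, rose from 5.91 ± 2.85 to 161 ± 34.7 (27.7-fold). Chga, a protein of secretory granules, was 19.9-fold and Trp73, a transcription factor of the p53 family, 18.7-fold higher. Nhlh2 and Trp73 are also members of the fixed list of Cajal-Retzius and preplate genes. Xkr7, Cbln2 and Plcb1 completed the 10 highest. Adjusted p-values of these 10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were led by 1.39e-08 for Nhlh2. The DP libraries lay above all PP libraries, as the rule for naming required.

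Genes of the radial glia, the dividing cells that line the ventricle, were lower in DP and those of intermediate progenitors higher. Of 30 radial glia genes, 24 were lower and 2 higher (camera adjusted p = 8.75e-12, adjusted p = 0.221 with an estimated correlation). Fabp7, a fatty acid binding protein, fell from 679 ± 92.4 to 200.01 ± 35.0 (3.39-fold lower). The glutamate transporter Slc1a3 fell from 415 ± 39.7 to 121 ± 24.8 (3.42-fold) and Ddah1 from 466 ± 51.2 to 119.8 ± 26.4 (3.89-fold). The homeobox gene Lhx2 went the other way, from 631 ± 29.4 to 818 ± 85.2. Of 30 intermediate progenitor genes, 27 were higher and 1, Sox21, lower (camera adjusted p = 3.17e-15, adjusted p = 0.182 with an estimated correlation). This list holds the sort gene Btg2, so it is not independent of the gate. Mfap4 rose from 19.8 ± 3.52 to 211 ± 31.7 (10.7-fold). Kif26b rose from 29.4 ± 10.3 to 319 ± 56.0 (10.9-fold) and the corepressor gene Rcor2 from 208 ± 17.5 to 687 ± 97.5 (3.30-fold). Named after their values were seen, Pax6 fell from 592 ± 18.5 to 367 ± 29.1 (1.61-fold) and Sox2 from 386 ± 19.1 to 243 ± 24.4 (1.59-fold), both factors of radial glia. Eomes, the hallmark factor of intermediate progenitors, rose from 235 ± 50.5 to 1162 ± 185 (4.95-fold) and the proneural factor Neurog2 from 368 ± 33.7 to 756 ± 141 (2.06-fold). Counts of list members adjusted over the list alone were the same as those over all features except where another count is given.

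Neuronal groups were higher in DP. Of 29 pan-neuronal genes, which include the sort gene Tubb3, 23 were higher and 2 lower (camera adjusted p = 2.79e-11, adjusted p = 0.246 with an estimated correlation). Among them Bcl11a rose from 185 ± 5.84 to 425 ± 41.2 and, named after its value was seen, the microtubule protein Dcx from 53.1 ± 31.4 to 747 ± 138 (14.1-fold). Gap43, a growth cone protein, fell from 32.3 ± 7.35 to 22.7 ± 1.76, a call lost without libraries L222, L223 and L224 together (adjusted p = 0.141). Of 22 neuronal splicing and RNA-binding protein genes, 18 were higher and 1 lower (camera adjusted p = 3.63e-08, adjusted p = 0.206 with an estimated correlation). Among them Celf3 rose from 18.7 ± 5.48 to 142 ± 21.1 and Rbfox2 from 132 ± 8.99 to 397 ± 56.9. Synaptic vesicle genes numbered 22 higher and 1 lower of 29, or 23 and 1 adjusted over the list alone (camera adjusted p = 8.49e-09, adjusted p = 0.182 with an estimated correlation). The vesicular glutamate transporter Slc17a7 rose from 1.45 ± 0.417 to 24.9 ± 2.77 (17.5-fold) and Syn2 from 2.95 ± 0.468 to 33.2 ± 6.33. Of 38 genes of ion channels and glutamate receptors, 22 were higher and 6 lower (camera adjusted p = 0.000632, adjusted p = 0.205 with an estimated correlation). The sodium channel gene Scn3a stood at 2.51 ± 1.06 in PP and 28.2 ± 7.40 in DP. Axon guidance genes were 27 higher and 8 lower of 45, or 28 and 9 adjusted over the list alone (camera adjusted p = 1.36e-05, adjusted p = 0.229 with an estimated correlation). The semaphorin receptor Nrp2 rose from 5.03 ± 1.12 to 73.9 ± 14.7 (14.8-fold) and Ntn4 fell from 73.0 ± 13.3 to 31.6 ± 3.29 (2.31-fold). Of 30 genes of cortical layer identity, 17 were higher and 5 lower (camera adjusted p = 0.000324, adjusted p = 0.205 with an estimated correlation). Bhlhe22 rose from 4.30 ± 0.0811 to 28.9 ± 6.63, Sox5 from 81.6 ± 11.4 to 138 ± 12.9 and, named after its value was seen, Tbr1 from 9.67 ± 5.81 to 146 ± 29.2 (15.3-fold). Nr4a2 fell from 98.2 ± 15.1 to 56.6 ± 7.43.

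Among groups of cell division and metabolism, 23 of 44 S phase genes were lower in DP and 0 higher, or 24 and 0 adjusted over the list alone (camera adjusted p = 9.83e-07, adjusted p = 0.472 with an estimated correlation). The uracil glycosylase gene Ung fell from 68.9 ± 4.17 to 31.8 ± 3.52 and the helicase subunit Mcm4 from 231 ± 11.7 to 139 ± 19.6. Of 54 G2 and M phase genes, 4 were higher and 0 lower, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.00508 upward, adjusted p = 0.772 with an estimated correlation). G2e3 stood at 149 ± 13.1 in PP and 218 ± 11.7 in DP, and Kif20b at 56.6 ± 5.29 and 79.3 ± 11.2. The upward call of this list was lost without DP library L223 (adjusted p = 0.247) and without libraries L222, L223 and L224 together (adjusted p = 0.232). Of 20 glycolysis genes, 14 were lower and 0 higher (camera adjusted p = 2.68e-06, adjusted p = 0.205 with an estimated correlation). Pdk1 fell from 62.4 ± 3.51 to 30.9 ± 1.13. The glucose transporter gene Slc2a1 fell from 91.5 ± 2.59 to 56.9 ± 3.40 and Aldoa from 225 ± 27.4 to 126 ± 10.6. Slc2a1 is also in the endothelial list and Aldoc in the radial glia list, and both lists were lower in this step. Globin genes, which moved the same way, together took 1.49%, 0.818% and 0.854% of the counts of PP libraries L222, L355 and L393. Of 30 Notch pathway genes, 11 were higher and 9 lower, or 11 and 10 adjusted over the list alone (camera adjusted p = 0.764, adjusted p = 0.877 with an estimated correlation). The ligand Dll1 rose from 186 ± 5.09 to 406 ± 22.3 (2.19-fold), and the receptors Notch2 and Notch3 fell from 880.5 ± 61.2 to 383 ± 90.4 and from 443 ± 43.1 to 188 ± 46.9. Of 29 Wnt signalling genes, 15 were higher and 10 lower (camera adjusted p = 0.0869, adjusted p = 0.472 with an estimated correlation). Wnt5a rose from 2.75 ± 0.934 to 38.3 ± 5.04 (13.8-fold) and Wnt7b from 30 ± 4.59 to 122 ± 15.5. The receptor Fzd8 fell from 327 ± 36.0 to 128 ± 6.95 and the secreted inhibitor Sfrp1 from 906 ± 59.1 to 355.9 ± 73.7. Reln of Cajal-Retzius cells and the hem gene Rspo2 rose in the same step (7.54-fold and 11-fold). The preset-correlation test of the Wnt list passed without PP library L355 (adjusted p = 0.0423) or without DP library L394 (adjusted p = 0.0475).

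Genes of blood and of other cell types also separated PP from DP. The lowest genes in DP included the haemoglobin genes Hbb-b2, Hbb-b1, Hba-a2 and Hba-a1, with Alas2, Spna1, Slc4a1, Phospho1 and Fam46c. Hbb-b1 stood at 4981 ± 1724 in PP and 22.6 ± 24.8 in DP (221-fold lower). Library L223 stood apart in DP: globin genes together held 120, 17 and 18.5 CPM in DP libraries L223, L356 and L394. Alas2, an enzyme of haem synthesis in red cells, stood at 192 ± 71.1 and 1.30 ± 1.07 (152-fold), and Slc4a1, the anion exchanger of red cells, at 94.9 ± 62.3 and 1.56 ± 0.805 (61.7-fold). Of 13 red blood cell genes, 11 were lower, or 13 adjusted over the list alone (camera adjusted p = 6.43e-08, adjusted p = 0.25 with an estimated correlation). Endothelial genes were lower for 9 of 13, or 10 adjusted over the list alone (camera adjusted p = 0.00813, adjusted p = 0.369 with an estimated correlation). Eng stood at 2.25 ± 1.43 in PP and 0.456 ± 0.0428 in DP. Of 9 pericyte genes 7 were lower, with Pdgfrb at 19.4 ± 2.56 and 6.65 ± 0.854 (camera adjusted p = 0.000729, adjusted p = 0.369 with an estimated correlation). Of 14 microglia genes 6 were lower, with Csf1r at 5.68 ± 0.628 and 3.38 ± 0.214 (camera adjusted p = 0.00833, adjusted p = 0.494 with an estimated correlation). This call was lost without libraries L222, L223 and L224 together (adjusted p = 0.0685).

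Markers of neurons and tissue borders moved upward. Of 15 Cajal-Retzius and preplate genes, 12 were higher in DP and 1 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.11e-07, adjusted p = 0.182 with an estimated correlation). Reln, the secreted protein of Cajal-Retzius cells, rose from 4.28 ± 1.38 to 31.9 ± 5.16 (7.54-fold) and Ebf2 from 0.503 ± 0.146 to 8.88 ± 1.68. Of 26 genes of ventral progenitors and interneurons, 11 were higher and 2, Maf among them, lower (camera adjusted p = 0.0114, adjusted p = 0.33 with an estimated correlation). The fall of Maf was lost in the single-read runs alone (adjusted p = 0.0519), and the list's call without PP library L393 (adjusted p = 0.055). Prox1 rose from 10 ± 1.74 to 69.5 ± 6.35. Dlx1, a homeobox gene of the ganglionic eminences, stood at 22.9, 8.09 and 1.68 CPM in PP libraries L222, L355 and L393 and at 83.5, 51.0 and 14.5 CPM in DP libraries L223, L356 and L394. Its rise (adjusted p = 0.027, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted) was lost without PP library L355 (0.0861), DP library L223 (0.0915) or DP library L356 (0.0536), and in a fit of PP and DP alone (0.0538). Of 11 genes of the choroid plexus and the cortical hem, the signalling centre at the edge of the cortex, 8 were higher and 0 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.000543, adjusted p = 0.182 with an estimated correlation). The Wnt agonist genes Rspo3 and Rspo2 rose from 1.53 ± 0.141 to 18.3 ± 1.85 and from 1.39 ± 0.627 to 15.4 ± 2.15. Ttr, the main transcript of choroid plexus, stood at 55.3, 14.1 and 28.7 CPM in PP libraries L222, L355 and L393 and at 52.8, 7.44 and 4.97 CPM in DP libraries L223, L356 and L394.

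**Figure D2:**
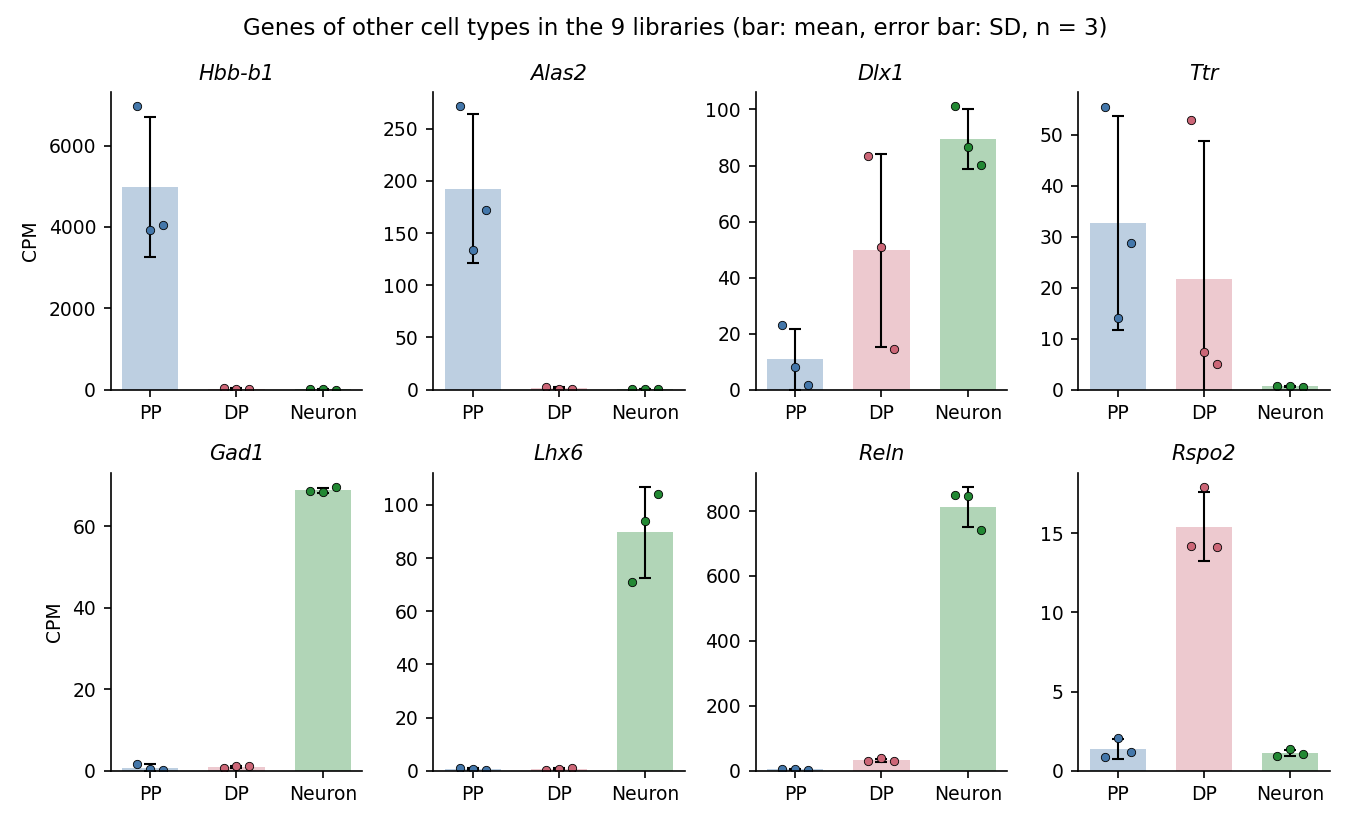
CPM of Hbb-b1, Alas2, Dlx1, Ttr, Gad1, Lhx6, Reln and Rspo2 (y axis) in PP, DP and Neuron (x axis), with bars for the mean, error bars for the SD, which end at 0 where the SD exceeds the mean, and points for the 3 libraries of each group. Hbb-b1 and Alas2 stood high in PP, Gad1, Lhx6 and Reln in Neuron and Rspo2 in DP. The Dlx1 and Ttr libraries of PP and DP spread widely.

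Over 18143 annotated genes tested, 3827 were higher and 3668 lower in DP than in PP by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, which is 41.3%. Among them, 1284 were higher and 1132 lower by at least 2-fold. For 10648 genes no difference was detectable. In the simulations, a change of 1.5-fold was found in 59.7% of the changed genes, which is not the power of this comparison. The authors' deposited table calls 3910 genes higher and 3632 lower at the same threshold. Of the 7495 genes called here, 7215 had the same call and direction in the authors' deposited table.

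The comparison of Neuron with DP asks what changes as differentiating progenitors become neurons. The 10 lowest genes in Neuron included factors of progenitors. Zfp36l1, an RNA decay factor, fell from 241 ± 53.6 to 1.72 ± 0.240 (139-fold lower, adjusted p = 7.85e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The proneural factor Neurog1 fell from 53.0 ± 7.94 to 0.430 ± 0.155 (123-fold), and Hes1, an effector of Notch signalling, from 60.2 ± 13.9 to 0.665 ± 0.110 (89.3-fold). Lfng, a modifier of Notch receptors, fell from 72.7 ± 24.1 to 0.703 ± 0.261 (102-fold). Mybpc1, Prelp, S1pr1, Plce1, Mlc1 and Lamb2 were the other 6 of the 10 lowest. Receptors and synaptic genes were among the highest. Grik3, a kainate receptor, rose from 3.26 ± 0.318 to 477 ± 29.5 (146-fold), and Rph3a, a synaptic vesicle protein, from 0.338 ± 0.126 to 52.8 ± 7.25 (log2 7.30). Hs3st4 rose from 0.259 ± 0.134 to 43.3 ± 7.65 (170.0-fold) and the interneuron factor Lhx6 from 0.584 ± 0.293 to 89.6 ± 17.0 (153-fold). Sst, the interneuron peptide somatostatin, rose from 0.0765 ± 0.0327 to 31.2 ± 8.60, with 10 reads in all over the DP libraries. Cntnap3, Gpr22, Rasgrf1, Drd1a and Lrfn5 were the other 5.

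Cell division genes were lower in Neuron almost throughout. All 44 S phase genes tested were lower (camera adjusted p = 3.41e-19, adjusted p = 0.221 with an estimated correlation). Mcm6 stood at 212 ± 18.8 in DP and 24.0 ± 3.26 in Neuron. Of 54 G2 and M phase genes, 53 were lower (camera adjusted p = 9.9e-20, adjusted p = 0.246 with an estimated correlation). Hmgb2 stood at 158 ± 22.5 and 7.76 ± 2.02. Radial glia genes were lower for 29 of 30 (camera adjusted p = 5.77e-13, adjusted p = 0.205 with an estimated correlation). The matrix protein gene Tnc fell from 154 ± 16 to 1.99 ± 0.413 (76.3-fold) and Gli3 from 333 ± 53.5 to 15.9 ± 2.28 (20.9-fold). Ptprz1 rose from 254 ± 52.9 to 518 ± 55.5. Of 30 intermediate progenitor genes, 24 were lower and 2 higher (camera adjusted p = 7.69e-07, adjusted p = 0.291 with an estimated correlation). Mfap4 fell from 211 ± 31.7 to 61.7 ± 17.2, and Pdzrn3 rose from 35.3 ± 10.1 to 117 ± 19.6. Eomes, named after its value was seen, fell from 1162 ± 185 to 81.8 ± 30.7 (14.2-fold). Pax6 and Sox2, also named afterwards, fell to 27.3 ± 6.24 and 37.3 ± 9.02 (13.4-fold and 6.52-fold lower). Notch pathway genes were lower for 23 of 30 and higher for 6 (camera adjusted p = 0.000802, adjusted p = 0.182 with an estimated correlation). Notch3 fell from 188 ± 46.9 to 3.99 ± 0.240 (47.1-fold), and Nrarp from 146 ± 23.7 to 10.2 ± 1.77. The ligand Dner rose from 12 ± 1.19 to 161 ± 4.25. Of 29 Wnt signalling genes, 24 were lower and 2 higher (camera adjusted p = 1.29e-07, adjusted p = 0.182 with an estimated correlation). The cyclin gene Ccnd1 fell from 95.7 ± 0.688 to 3.73 ± 0.457 (25.7-fold). Fzd8 fell from 128 ± 6.95 to 13.5 ± 0.995 and Sfrp1 from 355.9 ± 73.7 to 103 ± 9.99, and Wnt7b rose from 122 ± 15.5 to 572 ± 17.4.

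Neuronal groups rose further. Pan-neuronal genes were higher for 28 of 29, Tubb3 included, and lower for 0 (camera adjusted p = 7.18e-15, adjusted p = 0.205 with an estimated correlation). Syt1, the calcium sensor of vesicle release, rose from 3.27 ± 0.219 to 148 ± 6.51 (45.2-fold). Gap43 rose from 22.7 ± 1.76 to 286 ± 16.4 (12.6-fold). Of 38 genes of ion channels and glutamate receptors, 37 were higher and 1, Grik2, lower (camera adjusted p = 6.15e-15, adjusted p = 0.141 with an estimated correlation). The potassium channel gene Kcna1 rose from 1.94 ± 0.308 to 127 ± 4.2 (65.5-fold). The calcium channel gene Cacna1e rose from 6.22 ± 0.973 to 377 ± 39.9 (60.6-fold) and Scn3a from 28.2 ± 7.40 to 179 ± 4.09. Synaptic vesicle genes were higher for 25 of 29 and lower for 4 (camera adjusted p = 4.65e-10, adjusted p = 0.182 with an estimated correlation). Sv2a stood at 18.1 ± 1.99 and 249.5 ± 9.72 and Slc17a7 at 24.9 ± 2.77 and 169.9 ± 3.65. Axon guidance genes were 34 higher and 10 lower of 45 (camera adjusted p = 8.27e-05, adjusted p = 0.246 with an estimated correlation). Plxnd1 rose from 9.64 ± 1.01 to 252 ± 42.2, Sema5a fell from 417 ± 32.7 to 47.6 ± 12.1 and Slit2 fell from 110.4 ± 13.2 to 37.5 ± 1.77. Layer identity genes were 23 higher and 6 lower of 30 (camera adjusted p = 1.08e-05, adjusted p = 0.182 with an estimated correlation). Bhlhe22 rose from 28.9 ± 6.63 to 287 ± 33.7 (9.94-fold). Sox5 rose from 138 ± 12.9 to 943 ± 27.6 (6.86-fold) and, named after its value was seen, Tbr1 from 146 ± 29.2 to 882 ± 28.2. Pou3f3 fell from 497 ± 17.7 to 203 ± 30.3 and Cux1 from 191 ± 27.7 to 94.2 ± 11.2. Splicing and RNA-binding protein genes were 15 higher and 4 lower of 22, or 15 and 5 adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.387 with an estimated correlation). Celf3 rose from 142 ± 21.1 to 552 ± 40.1 and Elavl2 fell from 392.8 ± 68.7 to 242 ± 3.65. Glycolysis genes split, 5 higher and 11 lower of 20 (camera adjusted p = 0.476, adjusted p = 0.822 with an estimated correlation). Aldoc, the aldolase of glial cells, fell from 205 ± 59.8 to 3.04 ± 0.494 (67-fold) and Pfkp rose from 6.83 ± 0.767 to 163 ± 16.3 (23.8-fold).

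Genes of neurons other than the projection neurons of the cortex stood beside these. Of 26 ventral progenitor and interneuron genes, 16 were higher in Neuron and 6 lower (camera adjusted p = 0.0231, adjusted p = 0.329 with an estimated correlation). Gad1, the enzyme that makes GABA, rose from 0.964 ± 0.279 to 68.9 ± 0.607 (71.2-fold) with 68.6, 68.6 and 69.6 CPM in the Neuron libraries. Erbb4 rose from 2.31 ± 0.0455 to 93.4 ± 15.7 (40.4-fold) and Gad2 from 8.09 ± 4.76 to 76.4 ± 6.86. Dlx1 stood at 101, 86.7 and 80.2 CPM in Neuron libraries L224, L357 and L395. The progenitor factor Olig2 fell from 6.70 ± 2.15 to 0.132 ± 0.109. Of 15 Cajal-Retzius and preplate genes, 12 were higher and 1, Ebf2, lower (camera adjusted p = 0.000894, adjusted p = 0.205 with an estimated correlation). Reln rose from 31.9 ± 5.16 to 812 ± 61.0 (25.4-fold) and Nxph3 from 1.66 ± 0.257 to 67.3 ± 6.22 (40.5-fold). Genes of the choroid plexus and the cortical hem were lower for 10 of 11 and higher for 1, Rspo3 (camera adjusted p = 0.00445, adjusted p = 0.182 with an estimated correlation). Rspo1 fell from 13.8 ± 1.49 to 0.256 ± 0.0725. Microglia genes were lower for 9 of 14, with Csf1r at 3.38 ± 0.214 and 1.52 ± 0.340 (camera adjusted p = 0.0498, adjusted p = 0.587 with an estimated correlation). That call was lost without DP library L356 (0.102), Neuron library L224 (0.104) or Neuron library L395 (0.0524), and without libraries L222, L223 and L224 together (0.0685). The microglia call was also lost in the single-read runs (0.161) or the paired-end runs (0.118) alone, and with a block of library-number sets. Endothelial genes were lower for 5 of 13, or 3 adjusted over the list alone (camera adjusted p = 0.0537, adjusted p = 0.505 with an estimated correlation). The list passed without PP library L393 (0.0199) or Neuron library L395 (0.0341), and with a block of library-number sets. Pericyte genes were lower for 4 of 9, or 3 adjusted over the list alone (camera adjusted p = 0.263, adjusted p = 0.772 with an estimated correlation). Red blood cell genes were lower for 6 and higher for 1 of 13 (camera adjusted p = 0.519, adjusted p = 0.88 with an estimated correlation).

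**Figure D3:**
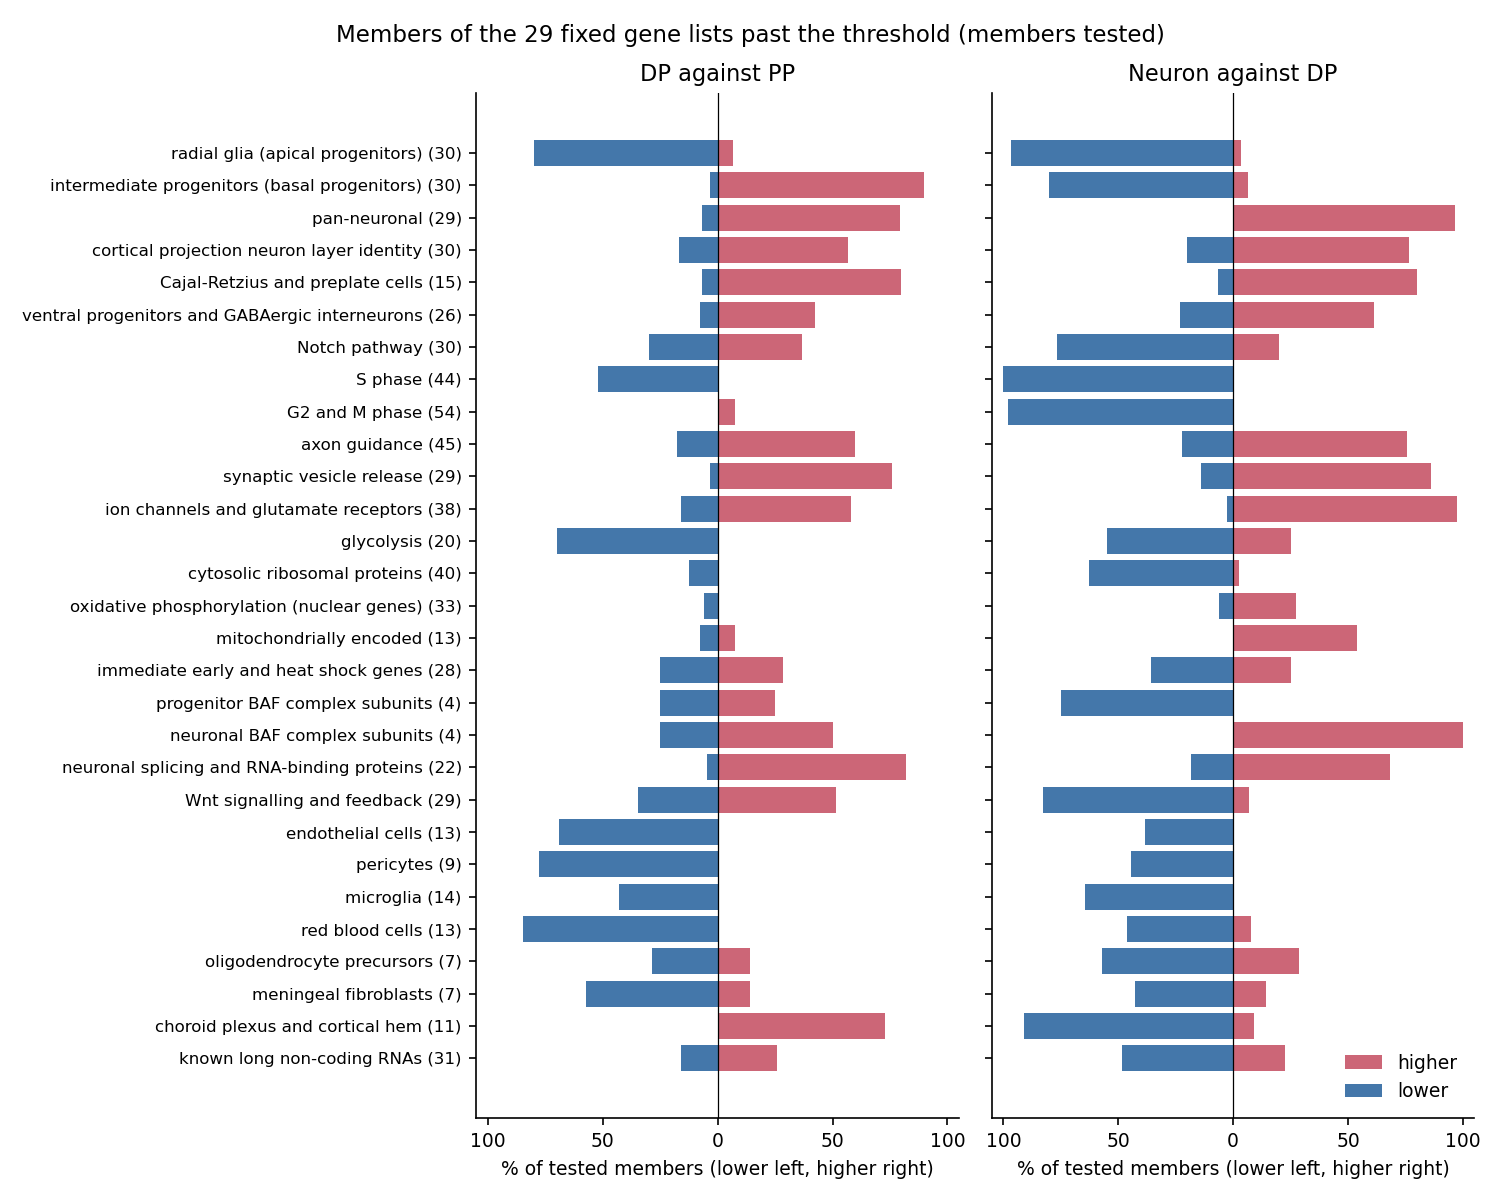
Percent of the tested members of each of the 29 gene lists (y axis, members tested in brackets) that were higher (right, red) or lower (left, blue) in DP against PP (left panel) and in Neuron against DP (right panel), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All 44 S phase genes and 53 of 54 G2 and M phase genes were lower in Neuron than in DP, against 23 and 0 lower in DP than in PP.

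In all, 5987 annotated genes were higher and 6214 lower in Neuron than in DP by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 67.2% of 18143 genes tested, with 2764 and 3196 changed by at least 2-fold. The authors' deposited table calls 6389 higher and 6016 lower. Of the 12201 genes called here, 11731 had the same call and direction in the authors' deposited table. With a preset correlation, 37 of the 58 list tests of both steps passed, and 0 passed with an estimated one.

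Between the ends of the lineage, Neuron against PP, receptor genes were among the highest and blood genes the lowest. Gpr26, a G protein coupled receptor, rose from 0.242 ± 0.0570 to 102 ± 16.4 (log2 8.70). March4, a ubiquitin ligase, rose from 0.247 ± 0.0582 to 93.3 ± 5.76 (log2 8.54), and Gabbr2, a GABA receptor subunit, from 0.0479 ± 0.0303 to 26.7 ± 2.83 (log2 9.12). Galnt9 and Drd1a were the other genes of the highest 5, at 12.9 ± 2.81 and 12.4 ± 1.5 in Neuron, with 3 and 4 reads in all over the PP libraries. Slc4a1, Spna1, Hbb-b1, Hba-a2 and Hbb-b2 were the lowest 5, with log2 -10.37 for Slc4a1 and -9.90 for Hbb-b1. Of 18143 annotated genes, 6633 were higher and 7026 lower (75.3%, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), with 3551 and 4081 changed by at least 2-fold.

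A set of genes was higher in DP than in both PP and Neuron, which sets it apart from genes that rise or fall along the whole lineage. Neurod4, a proneural factor of differentiating progenitors, stood at 2.30 ± 0.651 in PP, 36.0 ± 8.35 in DP and 0.722 ± 0.435 in Neuron (15.9-fold higher than PP, 50.2-fold lower in Neuron). The kinesin gene Kif26b stood at 29.4 ± 10.3 in PP, 319 ± 56.0 in DP and 28.1 ± 13.4 in Neuron, and Prox1, a homeobox factor, at 10 ± 1.74 in PP, 69.5 ± 6.35 in DP and 7.40 ± 2.54 in Neuron. Dll4, a Notch ligand, stood at 1.38 ± 0.0922 in PP, 14 ± 0.889 in DP and 1.17 ± 0.186 in Neuron. Endothelial cells also express Dll4, and their receptor gene Kdr stood at 4.50 ± 2.43 in PP, 6.11 ± 0.478 in DP and 1.27 ± 0.554 in Neuron. The endothelial list as a whole went the other way from Dll4 in the first step. Of its 13 genes tested, 9 were lower and 0 higher in DP than in PP, with a median log2 fold change of -1.16. Wnt8b, Wnt2b, Rspo1 and Rspo2, signalling genes of the cortical hem and the dorsal midline, peaked in DP too, Wnt8b at 1.86 ± 0.719 in PP, 26.0 ± 5.73 in DP and 0.355 ± 0.0441 in Neuron. Thrb, Prelp, Sema3g and Tmem132c completed the leading 12. Conversely, Sparcl1, a secreted matrix protein, stood at 20.4 ± 0.948 in PP, 4.13 ± 0.739 in DP and 33.1 ± 5.34 in Neuron, lower in DP than in both. The calcium-dependent kinase Camk1d stood at 36.7 ± 3.79 in PP, 8.99 ± 1.02 in DP and 40.0 ± 2.87 in Neuron and the protease Adamts18 at 85.7 ± 12.5 in PP, 21.3 ± 1.84 in DP and 127 ± 8.07 in Neuron. Diras2, Zcchc12 and Ntm completed the leading 6.

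There were 772 annotated genes higher in DP than in both and 828 lower, against 2249 higher and 1973 lower at each step, both changes past edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The authors' deposited table gives 753 and 829 at the same threshold. Both steps share the DP libraries, whose chance deviations push a gene up in one step and down in the other. Lists drawn independently with the observed numbers of calls would share 1311 and 1210 genes, more than were seen. Across 18627 features, which are not independent replicates, the log2 fold changes of the steps correlated at 0.26 (covariance 0.409), against -0.5 (covariance -0.025) in 20 simulations with no change between groups. Where nothing changes, the shared libraries alone give a correlation near -0.5, so the simulated value is no reference for data in which many genes change. The 3 DP libraries were not split between the steps, so the part of the shared libraries in the overlap was not measured.

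**Figure D4:**
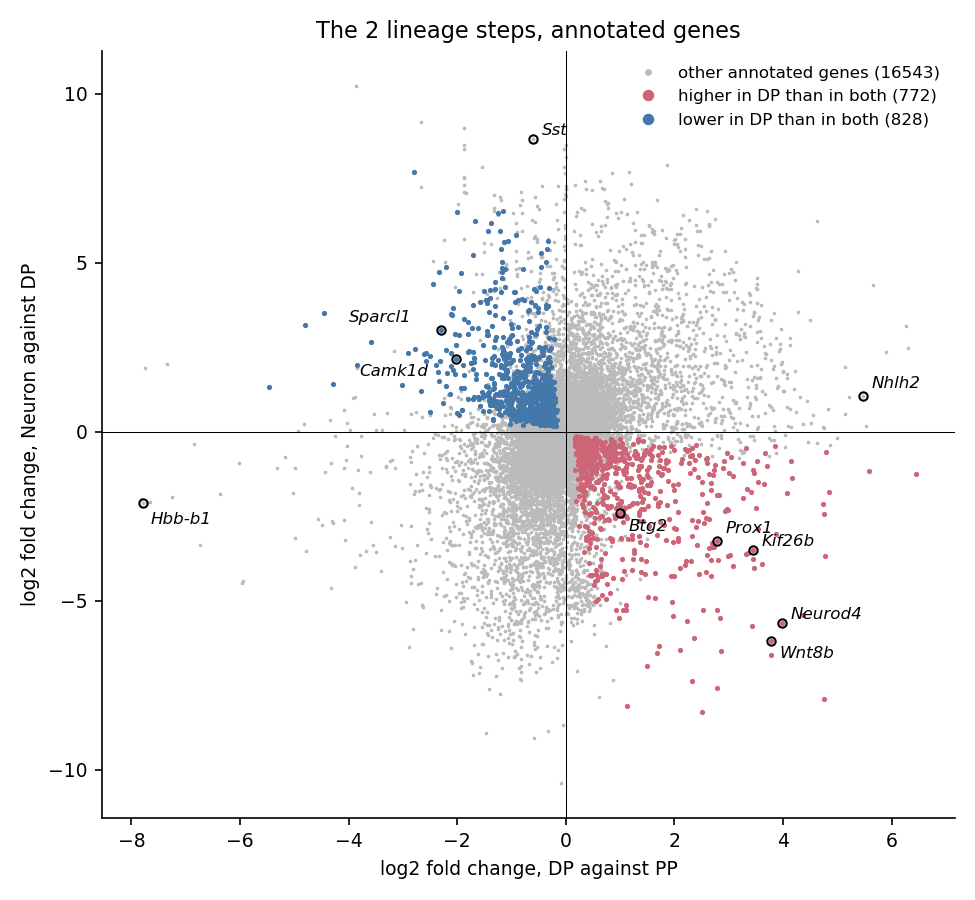
Fitted log2 fold change of each of 18143 annotated genes in DP against PP (x axis) and in Neuron against DP (y axis), with 772 genes higher in DP than in both in red, 828 lower in DP than in both in blue and the others in grey. Neurod4, Wnt8b, Kif26b and Prox1 lie at the lower right and Sparcl1 and Camk1d at the upper left.

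Long non-coding RNAs are named in the title of the series as its subject. Miat, a nuclear RNA of neural cells, stood at 1041 ± 119 in PP, 3837 ± 667 in DP and 2099.6 ± 96.4 in Neuron, 3.68-fold higher in DP than in PP and 1.83-fold lower in Neuron than in DP. Rmst, an RNA of neural differentiation, stood at 6.12 ± 2.44 in PP, 35.4 ± 5.37 in DP and 6.83 ± 0.638 in Neuron, a peak in DP of 5.73-fold over PP. The imprinted neighbours Meg3 and Rian rose along the lineage. Meg3 stood at 46.1 ± 9.88 in PP, 127 ± 21.9 in DP and 754 ± 54.7 in Neuron and Rian at 20.5 ± 3.58 in PP, 60.0 ± 11.7 in DP and 188 ± 17.4 in Neuron. Sox2ot, which overlaps Sox2 so that reads can be shared, fell from 86.0 ± 3.06 to 26.3 ± 4.73 in DP (3.27-fold), and the imprinted RNA H19 stood at 62.4 ± 16.6 in PP, 28.3 ± 8.66 in DP and 4.03 ± 1.19 in Neuron. Among long non-coding RNAs known by a model or clone number, Gm17325 rose from 0.226 ± 0.0836 to 4.92 ± 0.396 (22.1-fold) and A730020E08Rik from 0.520 ± 0.304 to 8.48 ± 1.38 (16.8-fold) in DP. C030005K06Rik fell from 6.35 ± 0.663 to 0.865 ± 0.233 (7.37-fold) and Gm20515 from 8.43 ± 0.259 to 1.28 ± 0.430 (6.57-fold), and Gm17591 fell from 25.7 ± 9.71 to 0.113 ± 0.0258 (218-fold) in Neuron.

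Of 1465 annotated long non-coding RNAs tested, 171 were higher and 341 lower in DP than in PP, 320 higher and 552 lower in Neuron than in DP, and 37 higher and 41 lower in DP than in both (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment at 0.05 over all features). The 341 became 199 without DP library L356 and 221 without PP library L393. The 41 became 17 without DP library L356, 21 without PP library L222, 26 without PP library L393, 26 without Neuron library L357 and 22 without libraries L222, L223 and L224 together. In the list of known long non-coding RNAs, 8 of 31 were higher and 5 lower in DP than in PP (camera adjusted p = 0.764, adjusted p = 0.909 with an estimated correlation). In Neuron against DP, 7 were higher and 15 lower (camera adjusted p = 0.409, adjusted p = 0.772 with an estimated correlation), with Snhg11 rising from 1.35 ± 0.358 to 34.4 ± 3.81 (25.4-fold). Antisense RNAs such as Gm13425 were left undescribed because their reads cannot be told from those of the opposite strand. The counts of annotated long non-coding RNAs still include antisense, sense-overlapping and sense-intronic RNAs and were not split by class. Some of these changes can therefore be those of an overlapping gene.

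The authors' tables also hold 630 transcripts outside the annotation. XLOC_001201 (chromosome 1, 155551636 to 155583684, mm9, 3795 bases from Rgs16 and in no annotated gene) stood at 0.465 ± 0.138 in PP, 5.77 ± 0.602 in DP and 0.843 ± 0.299 in Neuron, 12.6-fold higher in DP than in PP and 6.89-fold lower in Neuron. XLOC_001070 (chromosome 1, 135978184 to 135981128) lay 2487 bases from the sort gene Btg2, shared its pattern and stood at 0.424 ± 0.0713 in PP, 3.0 ± 0.332 in DP and 0.466 ± 0.142 in Neuron. XLOC_023746 (chromosome 18, 72844371 to 72853064) and XLOC_009667 (chromosome 12, 28283003 to 28303748) also peaked in DP, at 5.66 ± 1.28 and 5.78 ± 1.06. XLOC_005186 (chromosome 10, 94593364 to 94608492, 28888 bases from Cradd) rose from 0.194 ± 0.0988 to 6.10 ± 1.27 in DP (29.9-fold). XLOC_034392 (chromosome 4, 154022087 to 154033688), which overlaps the long non-coding RNA gene Gm13110 so that their reads can be shared, fell from 11.3 ± 2.04 to 2.07 ± 0.185 (5.46-fold). XLOC_016574 (chromosome 15, 32708788 to 32725822, 82692 bases from Sema5a) fell from 17.6 ± 1.45 to 4.65 ± 0.861. In Neuron, XLOC_009804 (chromosome 12, 51050130 to 51141077, 301141 bases from Prkd1) rose from 0.141 ± 0.0496 to 11.8 ± 1.67 (82.8-fold). XLOC_012201 (chromosome 13, 48123686 to 48139168, 432 bases from the long non-coding RNA A330033J07Rik) fell from 20 ± 3.56 to 0.364 ± 0.181 (54.1-fold). Exons and strands of these transcripts were not analysed here.

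At an adjusted p of 0.05, the authors' deposited table holds 140 unannotated transcripts higher and 86 lower in DP than in PP, and 217 higher and 170 lower in Neuron than in DP. By the authors' deposited tables, 43 were higher in DP than in both and 9 lower. Log2 fold changes in the authors' deposited table were 3.62 and -2.74 for XLOC_001201 and 2.80 and -2.64 for XLOC_001070, for DP against PP and Neuron against DP. Of 484 tested here by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 133 were higher and 86 lower in DP than in PP, 174 higher and 164 lower in Neuron than in DP, and 42 higher and 9 lower in DP than in both. These transcripts took 0.22% to 0.362% of the counts of a library.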

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

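The block of library-number sets and the loss of libraries L222, L223 and L224 together were chosen after the data were seen. Counts of annotated genes in Neuron against DP and Neuron against PP stayed within 1.5 times under each alternative run except a test against a fold of 1.5. No list test or named gene called here changed direction. Which direction held more genes did change. Neuron against DP had 5987 higher and 6214 lower here, 6164 and 5913 with DESeq2, and 6214 and 5955 with RLE size factors. Genes higher and lower in DP than in both were 772 and 828 here, 825 and 795 with limma-voom, and 802 and 732 with no filter. Leaving out 1 library gave 3245 to 4062 genes higher and 2756 to 3724 lower in DP than in PP. It gave 5565 to 6127 and 5685 to 6265 in Neuron than in DP, 6375 to 6917 and 6658 to 7139 in Neuron than in PP, and 612 to 839 higher and 611 to 811 lower in DP than in both. Long non-coding RNAs lower in DP than in PP ranged from 199 to 404, those lower in DP than in both from 17 to 41, and list tests called from 37 to 40. A test against a fold of 1.5 gave 1317 and 981 genes in DP against PP, 3323 and 3501 in Neuron against DP, 4186 and 4515 in Neuron against PP, and 201 and 158 higher and lower in DP than in both. For long non-coding RNAs it gave 95 higher and 104 lower in DP than in PP, about 3.6e+02 lower in Neuron and 18 and 9 in DP against both. For unannotated transcripts it gave 49 lower in DP and 2 lower in DP than in both. At an adjusted p of 0.01, 2340 genes were lower in DP than in PP and 481 and 471 higher and lower in DP than in both. For long non-coding RNAs these counts were about 1.7e+02, 21 and 15, and 4 unannotated transcripts were lower in DP than in both. A mean of at least 1 CPM, which tests fewer features, gave 106, 227, 175 and about 3.6e+02 long non-coding RNAs higher and lower at each step, with 22 and 26 in DP against both. Unannotated transcripts numbered 54, 39, 61 and 76, with 17 and 5. Single-read runs alone, with fewer reads, gave 219 long non-coding RNAs lower in DP than in PP, 212 higher in Neuron than in DP and 17 lower in DP than in both. Unannotated transcripts numbered 79, 51, 110 and 109, with 26 and 5. A fit of only the groups compared gave 27 long non-coding RNAs lower in DP than in both (the cause was not tested), and the loss of libraries L222, L223 and L224 gave 22. The authors' adjusted p under 0.01 left 5 unannotated transcripts lower in DP than in both. With an estimated correlation, 0 list tests passed, where the preset one gave 37.

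A block of replicate numbers could not be fitted, since the columns carry library numbers only. Deviations from the group mean correlated at 0.08 to 0.5 within the 9 pairs of libraries of 1 number set and at -0.48 to 0.2 in others. The limit was 0.1 for every pair, and 1 pair (L222 and L223) was under it. The main test therefore left the sets unpaired, and a pairing stays open. Each of the 9 libraries lay closest to its own set, a hint from the data. Library numbers of a set also run consecutively over PP, DP and Neuron, and the sample titles number the replicates alike in each fraction. Whether the libraries of a set came from a shared sort is not given in the sources used here. The block gave 4655 annotated genes higher and 4635 lower in DP than in PP, where the main test gave 3827 and 3668. It gave 1045 higher and 1083 lower in DP than in both, where the main test gave 772 and 828. With the block, 14 unannotated transcripts were lower in DP than in both (the cause was not tested). With it the microglia call in Neuron against DP was lost (adjusted p = 0.0642), and the endothelial (0.0389), mitochondrial (0.0422) and oxidative phosphorylation (0.0465) lists passed in that step. Across alternatives, 392 counts stayed within 1.5 times and 54 did not. List tests kept their side of the threshold 746 times, lost it 48 times and gained it 18 times, and named genes 12367, 364 and 98 times. Other scalings moved the median log2 fold change by 0.029 or less in size, and the share of changed annotated genes that were higher lay between 48.6% and 51.1% here and between 48.9% and 51.4% under them. Small changes can be missed: a simulated change of 1.5-fold was recovered in 59.7% of the changed genes and one of 4-fold in 99.1%. Recovery was not split by level or depth. The simulations changed far fewer genes than are called in the data, so these shares are not the power of the real comparisons.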

Other observations

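The tests of free RNA, of striatal tissue and of choroid plexus tissue were chosen only after the results they bear on were seen. Neuronal and progenitor subunit genes of the BAF chromatin remodelling complex moved apart in Neuron. Of 4 neuronal subunit genes, 2 were higher and 1 lower in DP than in PP (camera adjusted p = 0.28, adjusted p = 0.534 with an estimated correlation). All 4 were higher in Neuron than in DP (camera adjusted p = 0.00107, adjusted p = 0.182 with an estimated correlation). Actl6b stood at 0.880 ± 0.636 in PP, 8.69 ± 1.77 in DP and 151 ± 6.01 in Neuron. Of 4 progenitor subunit genes, 1 was higher and 1 lower in DP than in PP, with a median log2 fold change of 0.05, a mean of -0.02 and a camera test pointing down (camera adjusted p = 0.992, adjusted p = 0.992 with an estimated correlation). In Neuron against DP 3 were lower (camera adjusted p = 0.0339, adjusted p = 0.205 with an estimated correlation). Actl6a fell from 99.5 ± 3.97 to 55.3 ± 2.73 and Ss18 from 99.0 ± 6.39 to 50.9 ± 5.12. Immediate early and heat shock genes split: 8 of 28 were higher and 7 lower in DP than in PP (camera adjusted p = 0.981, adjusted p = 0.992 with an estimated correlation). There were 7 higher and 10 lower in Neuron than in DP, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.538, adjusted p = 0.795 with an estimated correlation). Fos rose from 22.3 ± 2.72 to 51.4 ± 16.1 and Jun fell from 734 ± 98.0 to 339.8 ± 41.7 in DP.

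Cytosolic ribosomal protein genes were lower for 5 of 40 in DP than in PP, or 2 adjusted over the list alone (camera adjusted p = 0.28, adjusted p = 0.772 with an estimated correlation). In Neuron against DP 25 were lower and 1 higher (camera adjusted p = 0.00197, adjusted p = 0.369 with an estimated correlation). Rps18 stood at 84.5 ± 1.53 in DP and 58.1 ± 3.45 in Neuron. Nuclear genes of oxidative phosphorylation were lower for 2 of 33 in DP, or 0 adjusted over the list alone (camera adjusted p = 0.54, adjusted p = 0.909 with an estimated correlation). In Neuron 9 were higher and 2 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.214, adjusted p = 0.825 with an estimated correlation). Without PP library L393 the ribosomal and oxidative phosphorylation lists passed in DP against PP (adjusted p = 0.0468 each). Of 13 mitochondrially encoded genes, 1 was higher and 1 lower in DP, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.476, adjusted p = 0.772 with an estimated correlation). In Neuron 7 were higher (camera adjusted p = 0.0712, adjusted p = 0.369 with an estimated correlation). The gene mt-Co1 stood at 3024 ± 26.7 and 3861 ± 107, and the list passed without DP library L394 (0.0475). Of 7 oligodendrocyte precursor genes, 1 was higher and 2 lower in DP (camera adjusted p = 0.943, adjusted p = 0.944 with an estimated correlation). In Neuron 2 were higher and 4 lower (camera adjusted p = 0.714, adjusted p = 0.795 with an estimated correlation). Meningeal fibroblast genes were lower for 4 of 7 and higher for 1 in DP (camera adjusted p = 0.0884, adjusted p = 0.556 with an estimated correlation). Their most counted gene, Col3a1, stood at 4.40, 8.93 and 44.1 CPM in PP libraries L222, L355 and L393. That list passed without PP library L222 (0.00101), DP libraries L223 (0.017), L356 (0.028) or L394 (0.0234), or Neuron libraries L224 (0.0149), L357 (0.013) or L395 (0.0125). In Neuron against DP, 1 meningeal gene was higher and 3 lower (camera adjusted p = 0.42, adjusted p = 0.794 with an estimated correlation).

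Red blood cell genes were higher in PP than in DP and Neuron, with globin genes taking 1.49%, 0.818% and 0.854% of the counts of PP libraries L222, L355 and L393. Transcription of globin by the neural progenitors themselves predicts a median log2 fold change of DP against PP above -1 in other erythroid genes. It was -2.1 (quartiles -4.36 and -1.62) over 16 erythroid genes outside the fixed list and -1.5 (quartiles -2.91 and -1.18) without PP library L222. Over the 5 of these genes at 10 CPM or more in PP it was -1.67, and -1.41 without L222. These medians lie under the prediction. The upper quartile also stayed under -1 with each library left out in turn. Without L222 it was -1.18 over the 16 genes and -1.28 over the 5, with the highest gene at -0.44 and -0.57. These values argue against such transcription for the genes covered, although the bound of -2 written against it was not reached without L222. The lowest PP library held 68.4 times the globin CPM of the highest DP or Neuron library. That ratio restates the difference to be explained, so it is no independent test of free RNA carried into all fractions. Among the erythroid genes Fech stood at 85.7 ± 27.4 in PP, 21.0 ± 1.13 in DP and 23 ± 0.544 in Neuron and Slc25a37 at 95.9 ± 28.0 in PP, 30.2 ± 3.11 in DP and 4.27 ± 0.331 in Neuron, both named after their values were seen, and 5 of the 16 reached 10 CPM in PP, 4 in DP and 3 in Neuron. Red blood cells or their precursors among the unlabelled cells of the PP gate stay open, since the bound of -2 written for them beforehand was reached by the median of -2.1 but not by that of -1.5 without L222.

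Interneuron genes were higher in Neuron than in DP, with Lhx6 at 70.8, 94.1 and 104 CPM in Neuron libraries L224, L357 and L395, although the ganglionic eminences were removed at dissection. Interneurons sorted into the Neuron gate stay open: 66.7% of 9 interneuron genes outside the fixed list had a log2 fold change of at least 2, under the 75% written beforehand and above the bound that would exclude them. In the fixed list, 3 of the 26 genes are in another list, and Nxph1, outside it and named after its value was seen, stood at 0.342 ± 0.196 in DP and 29 ± 4.97 in Neuron. Striatal tissue left in the dissection predicts that interneuron genes vary between Neuron libraries as striatal genes do. The highest library over the lowest had a median of 1.45 (quartiles 1.24 and 1.71) over 16 called interneuron genes and of 4.18 (quartiles 2.01 and 13.51) over 11 striatal genes, with Isl1 at 11.6, 1.83 and 0.258 CPM, but this leaves such tissue open, since 1 of the 11 striatal genes reached 10 CPM in Neuron and 2 are in another list.

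Of 11 genes of the choroid plexus and cortical hem list, 7 were higher in DP than in both PP and Neuron, while Rspo3 was higher still in Neuron. Cells of the hem in the DP gate stay open: 5 hem genes outside the fixed list had a median log2 fold change of 0.31 in DP against PP (quartiles 0.27 and 1.01, lowest -1 for Bambi, named after its value was seen) and of -2.36 in Neuron against DP, the first under the bound of 0.5 written to exclude them, but over it without PP library L393 (0.86) or DP library L356 (0.51). Bmp7, the only one of the 5 at 10 CPM or more in DP and named after its value was seen, stood at 8.92 ± 1.43 in PP, 11.1 ± 1.76 in DP and 2.2 ± 0.222 in Neuron, and 2 of the 11 genes of the fixed list are in another list. Choroid plexus tissue predicts that hem genes vary between DP libraries as Ttr does; the highest library over the lowest was 1.27 at the median of the 7 genes, Folr1 of the choroid plexus among them, and 10.63 for Ttr, a single gene that leaves such tissue open. Expression of these genes by differentiating progenitors themselves, the biological explanation the groups give, may hold as well and was not tested.

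Other splits of the 6 libraries of 2 groups number 10 with the real one, too few for a share under 0.05. The real split gave 7495, 12201 and 13659 annotated genes in DP against PP, Neuron against DP and Neuron against PP, with 0 the highest of the others, so 1 of the 10 splits was as large. For long non-coding RNAs (512 and 872) and unannotated transcripts (219 and 338), 1 of the 10 splits was as large as well, with 0 the highest other. For list tests the real split called 18 in DP against PP with 16 the highest other (1 of the 10), and 19 in Neuron against DP with 20 the highest other (5 of the 10). For genes higher or lower in DP than in both, 2 of the 100 splits drawn from 840 were as large, the real one included, with 772 and 828 against 4685 and 5112, and for unannotated transcripts 2 of the 100, with 42 against 130. Splits that mix all groups inflate the spread and gave 0 or 1 genes of either kind, so these shares do not exclude chance. In 4 other splits PP or Neuron took the place of DP as a whole, and 821, 5112, 661 and 755 genes were lower there than in both others. The largest has the Neuron libraries L224, L357 and L395 in that place, which points to the structure of the samples.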
